A study of Mus musculus with 10 samples.

How the data were processed

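The study sequenced RNA from male mouse embryonic stem cells grown without feeders in serum and LIF. Per the labels' protocols, YTHDC1 fused to the Halo tag was captured on beads under a denaturing wash without nuclease digestion or fragmentation of the RNA, and the RNA was released with a protease. A Halo-GFP control is mentioned there but was not analysed here. The m6A samples carry the same protocol text, so the antibody and fragmentation of the m6A step are not given in the sources used here. Samples were grouped by title: 1 RIP and 1 RIP input, and 2 precipitates and 2 inputs for each Mettl3 genotype. The cell type label of the knockout samples reads wild type, and the title was followed. Nothing in the labels says whether the samples of a group came from separate cultures.

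The deposited files are 3 lists with 3 columns each (chromosome, start and end of each peak), so the unit of the values is position in bp. The authors deposited no score or fold with the peaks. Per the submitters' processing notes the build was mm10 and the tools included bcl2fastq, STAR 2.7, Trim Galore 0.6.4, HISAT2 2.2.0, SAMtools 1.9 and MACS2 2.1.2. Which of these served which step, the peak threshold and whether replicates were pooled are not given in the sources used here. The wild-type list is named in the labels of both wild-type precipitates and of 1 knockout precipitate, and the knockout list in the label of the other knockout precipitate alone. The m6A peaks all start and end on a 50 bp grid (100% in both lists) and the RIP peaks do not (0.513%), so the lists were not made by identical steps. No peaks overlap or touch within a list. Because a caller's reach grows with depth and enrichment, and neither is known here, the number and width of peaks in a list are not measures of the amount of m6A or of binding.

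Genes came from the RefSeq gene table of GRCm38.p6, whose chromosome coordinates are those of mm10. It holds 49997 gene models, of which 34614 protein-coding (21887) and long non-coding RNA genes (12727) were used. At most 6 peaks of a list lay past the last annotated gene of their chromosome. The table gives gene spans without exons, strand or sequence. The planned division into untranslated regions, coding exons and introns, the distance to stop codons and the search for the DRACH motif were therefore not run. In their place, peaks were classed by whether their midpoint lay in a gene span and within 200 bp of a span end, a substitute chosen after the files were seen. A midpoint in several spans went to the protein-coding gene and then to the shortest. Since the files carry no score, width took its place in every ranking, as foreseen in the plan.

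Peaks overlapped if they shared at least 1 bp, and an m6A peak was wild-type-only, knockout-only or shared on that basis. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. Overlap between lists was compared with 1000 random placements of each peak within the span of its gene (one-sided permutation p, smallest value 0.001). The share near span ends was compared with 20 such placements. Counts were compared with Fisher's exact test, two-sided, with Wald 95% intervals of the odds ratio and Benjamini-Hochberg adjustment over 14 comparisons of peak classes, 51 tests of gene lists against peak lists, or 17 comparisons of the genotypes over gene lists. Peaks and genes are not replicates, so these p-values compare the lists, not the conditions. Where the p-value was at or below 1e-300 the odds ratio alone is given. The cover by RIP peaks around m6A peak midpoints was read every 100 bp to 5 kb on both sides. Genes with a wild-type peak alone and a knockout peak alone were compared by the exact McNemar test.

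The tests, the gene lists, the rule for named genes and the main alternatives were fixed before the data were examined. Named genes were those with the 10 widest peaks in the wild-type-only, shared, knockout-only and RIP sets and in the RIP peaks on wild-type-only m6A peaks, up to 4 members of each gene list by widest wild-type m6A peak and up to 4 by widest RIP peak, and Mettl3, Ythdc1, Pou5f1, Sox2, Nanog, Klf4, Myc, Malat1, Neat1 and Xist. Genes with provisional names (Gm numbers and Rik names) counted in these ranks but are not printed, and 1 further gene that met the rule is not reported here. The gene lists covered pluripotency, 2-cell-like genes, m6A factors, retrotransposon silencing, chromatin regulators, nuclear and imprinted long non-coding RNAs, splicing factors, ribosomal proteins, replication-dependent histones, Zfp genes, immediate early and signalling genes, housekeeping genes and markers of 5 other lineages. A list of mitochondrially encoded genes matched 0 genes and was left out. Of the names asked for, 5 of 28 in the 2-cell-like list and 1 each in the lists of retrotransposon silencing (33 names), long non-coding RNAs (30) and mesoderm (16) had no match in the gene table.

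Alternatives included peaks above each list's median width (ties by position), an overlap of at least 50% of the shorter peak, peaks within 100 bp counted as overlapping, any overlap with a gene span in place of the midpoint, protein-coding genes only, Mantel-Haenszel estimates over 8 bins of peak width or 10 bins of gene span, and 10000 random gene lists matched on gene span. Before use, the placement test was tested on simulated data. In 20 runs with RIP peaks placed at random against the wild-type m6A list it made 2 calls. In 20 runs of the knockout against the wild-type list it made 1 call. It recovered 95.0% and 95.4% of a planted excess of 1145 and 323 peaks. These runs used fewer placements than the analysis. Their peaks were placed within gene spans by the rule of the test itself, so they cannot show the effect of real peaks confined to exons. The gene list test over 34614 genes called 0 of 100 random lists of 30 genes and 100 of 100 lists in which 50% of the members were given a peak. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.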

Results

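The series profiled RNA in male mouse embryonic stem cells, the cultured counterpart of the early pluripotent embryo. It asked which RNAs are bound by YTHDC1, the nuclear reader of N6-methyladenosine (m6A), and where m6A lies in cells with and without METTL3, the catalytic subunit of the enzyme that writes m6A on messenger RNA. The 10 samples were 1 pull-down of Halo-tagged YTHDC1 (RNA immunoprecipitation, RIP), 1 matched input, and 8 m6A immunoprecipitation samples: 2 precipitates and 2 inputs from Mettl3 wild-type cells and the same from Mettl3 knockout cells. The authors' 3 peak lists were analysed, 1 each for wild-type m6A (12368 peaks), knockout m6A (6764 peaks) and YTHDC1 RIP (30992 peaks). Each list gives positions only, with no height, read count or strand and no value per replicate. No difference below can therefore be set against a spread between replicates. All intervals and p-values cover the counting of peaks or genes in these lists, and the read depth behind the peaks is unknown.

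The widest m6A peaks found in the wild-type list and not in the knockout list lay in Plec, which encodes the cytoskeletal linker plectin (3250 bp, chromosome 15, 76174951 to 76178200), and in the receptor gene Notch2 (3100 bp, chromosome 3, 98146001 to 98149100). Others among the 10 widest lay in Tnrc6c, a scaffold of microRNA silencing (2700 bp), in Pkd1, which encodes polycystin-1 (2600 bp), and in Exoc8, a subunit of the exocyst (2550 bp). The widest wild-type peaks that overlapped a knockout peak lay in Spen, a transcriptional repressor that binds Xist RNA (4400 bp, chromosome 4, 141471501 to 141475900), in Dido1 (3050 bp), in Arhgap32 and in Dag1, which encodes dystroglycan (2800 bp each), in the imprinted retrotransposon-derived gene Peg10 (2600 bp) and in the histone-modifying enzyme genes Kat6b (2550 bp) and Kmt2a (2500 bp). No knockout peak was wider than 1450 bp. The widest seen only in the knockout list reached 1250 bp, in Raph1 and in Rrbp1, followed by Ppig (1050 bp), Ptma, which encodes prothymosin alpha, and Fam122b (1000 bp each), and Cd55, a complement regulator (950 bp, chromosome 1, 130448451 to 130449400). All coordinates are on mm10 and counted from 1.

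The wild-type list held more and wider peaks than the knockout list, with a median width of 400 bp against 250 bp and 6.15 Mb covered against 1.71 Mb. Of the wild-type peaks, 1434 (11.6%, exact 95% binomial interval 11 to 12.2%) overlapped a knockout peak by at least 1 bp, and 10934 did not. Conversely, 1445 knockout peaks (21.4%, 20.4 to 22.4%) overlapped a wild-type peak, and 5319 did not. Among knockout peaks in gene spans, 1383 overlapped the wild-type list, against 354 ± 15.6 (SD over 1000 placements) when each was moved at random within its own gene, a ratio of 3.90 (one-sided permutation p = 0.001, the smallest that 1000 placements can give). The gene table gave no exons, so how far shared exons account for this ratio was not tested. With each list restricted to its peaks above the median width, the overlapping share of wild-type peaks was 5.48% and the ratio 2.42. Over the 1466 overlapping pairs the widths in both lists had a median of 300 bp and a rank correlation, across peaks that are not independent replicates, of 0.0636. The label of 1 of the 2 knockout precipitates names the wild-type list, so how the samples were divided between the lists is not settled.

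Among the genes fixed beforehand, the widest wild-type peak of Sox2, of Klf4 and of Nanog overlapped no knockout peak. Sox2, a core pluripotency factor, held a 1300 bp wild-type peak (chromosome 3, 34650451 to 34651750) in the body of the gene, while its 150 bp wild-type peak nearer the span end (34650051 to 34650200) overlapped the 450 bp knockout peak. Klf4, another pluripotency factor, had 4 wild-type peaks, the widest of 1400 bp (chromosome 4, 55529651 to 55531050), and 1 knockout peak of 200 bp whose midpoint lay 124 bp from the end of the gene span. The homeobox gene Nanog had 1 wild-type peak (chromosome 6, 122713201 to 122713600) and 1 knockout peak (122707551 to 122707900) at the opposite end. Pou5f1, which encodes OCT4, had no wild-type peak and 1 knockout peak that crossed the span end, with its midpoint 51 bp inside. Myc had no m6A peak in either list. Ythdc1 itself carried 4 wild-type and 4 knockout peaks. Mettl3 held no peak in any list, which says nothing about its RNA level and does not check the genotype labels.

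Knockout-only peaks lay close to the ends of genes far more often than wild-type-only peaks. Within 200 bp of either end of the gene span lay 1561 of 5091 knockout-only peaks in genes (30.7%, 29.4 to 31.9%), 303 of 1372 shared peaks (22.1%, 19.9 to 24.4%) and 235 of 10416 wild-type-only peaks (2.26%, 1.98 to 2.56%). Random placement within the same genes put 1.5%, 1.2% and 0.494% of the respective peaks there. The odds ratio of knockout-only over wild-type-only peaks was 19.2 (95% interval 16.6 to 22.1), and that of shared over wild-type-only peaks 12.3 (10.2 to 14.7, Fisher's exact test, two-sided, adjusted p = 1.3e-148 over 14 comparisons). Whether an end is the transcription start or the polyadenylation site cannot be said from the gene table used, which gives no strand. The ratio depended on its definition. It was 33.3 within 100 bp, 4.35 within 500 bp, 4.25 when the nearest peak edge was used, and 69.0 for peaks above the median width. The first 3 of these settings were chosen after seeing the data. A peak over 400 bp wide that lies wholly inside its span cannot have its midpoint within 200 bp of an end. Random placement has the same bound. The median width was 400 bp in the wild-type and 250 bp in the knockout list. The ratios from midpoints, above all the 69.0, are therefore partly set by width.

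**Figure D1:**
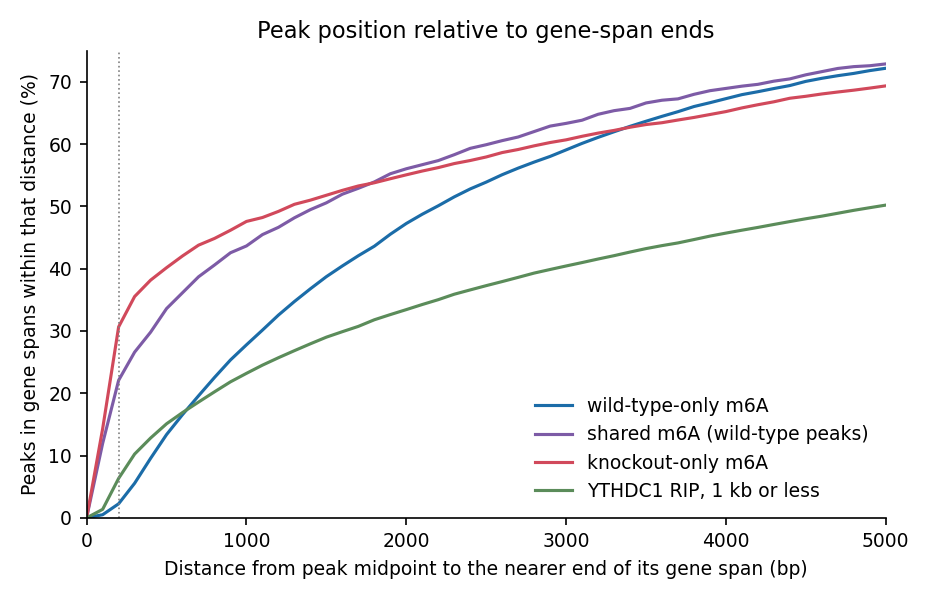
Cumulative share (%) of peaks in gene spans against the distance in bp from the peak midpoint to the nearer end of the span, for wild-type-only, shared and knockout-only m6A peaks and for RIP peaks of 1 kb or less. At the dotted line (200 bp) the curves stand at 2.26% for wild-type-only, 22.1% for shared and 30.7% for knockout-only m6A peaks.

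By location inside or outside genes, wild-type-only and knockout-only peaks were close. Gene spans held 95.3% (94.8 to 95.7%) of the first and 95.7% (95.1 to 96.2%) of the second, with an odds ratio of 0.901 (0.768 to 1.06, Fisher's exact test, two-sided, p = 0.201, adjusted p = 0.235). The direction of this ratio turned for peaks above the median width (1.56, Fisher's exact p = 0.000418), and with any overlap with a gene span counted it was 0.769 (p = 0.00238). The X chromosome carried 288 of 6764 knockout peaks (4.26%) and 290 of 12368 wild-type peaks (2.34%), an odds ratio of 1.85 (1.57 to 2.19, Fisher's exact test, two-sided, adjusted p = 7.8e-13). The span of Xist, the X-linked RNA of dosage compensation, held no wild-type peak and a knockout peak of 750 bp (chromosome X, 103481901 to 103482650). Without strand this peak cannot be assigned to Xist rather than to an RNA from the opposite strand.

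Zinc finger genes stood out in the wild-type list. Of 396 genes named Zfp, a list matched by name and not by function, 255 (64.4%, 59.5 to 69.1%) had a wild-type m6A peak and 58 (14.6%, 11.3 to 18.5%) a knockout peak. A peak in the wild-type list only was found in 204, against 7 with a peak in the knockout list only. The widest were in Zfp871 (2500 bp), Zfp715 (2450 bp) and Zfp553 (2050 bp), none with a knockout peak. Splicing factors and nuclear speckle proteins ran the other way, with 15 of 35 in the wild-type list and 29 in the knockout list (2 against 16 in 1 list only). Sfpq, a paraspeckle protein, had 0 wild-type and 4 knockout peaks, Rbm39 had 0 and 3, and Acin1 had 2 and 8, whereas Son, the scaffold of nuclear speckles, had 6 and 2. Ribosomal protein genes had a peak in the wild-type list for 3 of 80 and in the knockout list for 13 (1 against 11 in 1 list only), with Rpl41 and Rpl28 in both.

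Since the wild-type list covers more genes (4114 in it alone against 1491 in the knockout list alone), these counts were also set against all other genes. The odds ratio of wild-type alone over knockout alone was 11.1 (5.19 to 23.6) for Zfp genes (Fisher's exact test, two-sided, adjusted p = 1.5e-18 over 17 lists). By the same exact test it was 0.0448 (0.0103 to 0.195, adjusted p = 4.4e-07) for splicing factors, 0.0327 (0.00422 to 0.254, adjusted p = 2.4e-05) for ribosomal proteins and 0.0451 (0.00563 to 0.361, adjusted p = 0.000723) for replication-dependent histones, of which 1 had a wild-type peak alone and 8 a knockout peak alone. Housekeeping genes gave 0.181 (exact test, adjusted p = 0.0466), which rose to an adjusted p of 0.0522 when every gene a peak overlaps was counted. With peaks above the median width the odds ratio was 4.19 for Zfp genes (135 against 14), 0.0245 for splicing factors, 0.07 for histones and 0.0932 for housekeeping genes, and with every gene a peak overlaps it was 0.0148 for ribosomal proteins. In the exact McNemar test within each list, 4 of 17 lists passed: Zfp genes (adjusted p = 3.6e-50), splicing factors (0.00744), ribosomal proteins (0.027) and the immediate early and signalling genes (0.00744, 11 genes in the wild-type list alone, among them Socs3, Spry2, Ier5 and Ier2, and 0 in the knockout list alone). The last list did not pass against other genes (Fisher's exact test, adjusted p = 0.107), and the ribosomal proteins did not pass the McNemar test with peaks above the median width (0 against 6, adjusted p = 0.133).

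Chromatin and pluripotency genes had peaks in both m6A lists. Whether the knockout peaks mark m6A was not tested. Of 38 Polycomb, trithorax and remodelling genes, 30 had a wild-type and 23 a knockout peak, the widest wild-type ones in Kmt2a, in the acetyltransferase genes Crebbp (2050 bp) and Ep300 (2000 bp) and in the remodeller Arid1a (2000 bp). Of 30 pluripotency factors 21 and 19 had one, Tbx3 with 5 wild-type and 2 knockout peaks and Fgf4 with 1 and 0. The m6A writers, erasers and readers counted 17 and 16 of 23, with the widest wild-type peaks in Rbm15 (2400 bp) and Rbm15b (2200 bp), adaptors of the methyltransferase complex, neither with a knockout peak. Genes of retrotransposon silencing counted 22 and 18 of 32, led by the dioxygenase gene Tet2 (2000 bp, 7 wild-type and 6 knockout peaks). Each of these counts lay above that of other genes (odds ratios 9.42 to 17.8, Fisher's exact test, largest adjusted p = 5.2e-08), with odds ratios of 5.28 to 10.6 among protein-coding genes and 4.5 to 16 with peaks above the median width. None of these lists passed the McNemar test between genotypes.

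Over all 51 tests of a gene list against a peak list, 28 passed at an adjusted p of 0.05, 25 of them higher than other genes and 3 lower. The 3 lower ones were ribosomal proteins (adjusted p = 0.0002) and replication-dependent histones (9.5e-05) in the wild-type m6A list, and the 2-cell-like genes, markers of a rare embryo-like state, in the RIP list (0 of 23, exact 95% interval up to 14.8%, adjusted p = 0.00152). Against 10000 random lists matched on gene span these counts stayed below the random mean (3 against 7.42, 1 against 2.65 and 0 against 3.46) but did not pass (adjusted permutation p = 0.169, 0.671 and 0.0644). The same matching added calls for ribosomal proteins and histones in the knockout list (13 against 5.23 and 8 against 1.98, adjusted permutation p = 0.00775 and 0.00255) and for housekeeping genes in the wild-type list (8 against 2.88, 0.0145). The lists of neuroectoderm (4 of 17 genes with a wild-type m6A peak, among them Otx2 and Sox1), mesoderm (2 of 15), endoderm (1 of 17), trophoblast (2 of 15) and fibroblast markers (3 of 16) passed in no peak list, except that mesoderm genes were lower in the RIP list among protein-coding genes (1 of 15, exact test, adjusted p = 0.0136). Splicing factors in the wild-type list no longer passed among protein-coding genes or with peaks above the median width (adjusted p = 0.162 and 0.341, exact test). Among protein-coding genes the immediate early and the housekeeping genes no longer passed in the RIP list (exact test, adjusted p = 0.257 and 0.0753). The labels give polyA RNA for the m6A samples, and how far this selection bears on the histone counts was not tested. The lists do not give expression, and the other genes include unexpressed ones. Against genes with a peak in at least 1 list, a background chosen after seeing the data, 13 of the tests passed. The calls lost were those of every list higher in the RIP list (Zfp genes turned lower there, odds ratio 0.618) and, in the wild-type m6A list, those of pluripotency factors, m6A factors, retrotransposon silencing, splicing factors and immediate early genes, and the long non-coding RNAs in the knockout list. Zfp genes in the knockout list passed as lower (odds ratio 0.466). The tested peak lists select the genes of this background, and most of them enter through the RIP list. It therefore cannot tell expression apart from this selection. How far expression accounts for the calls against all other genes was not tested.

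**Figure D2:**
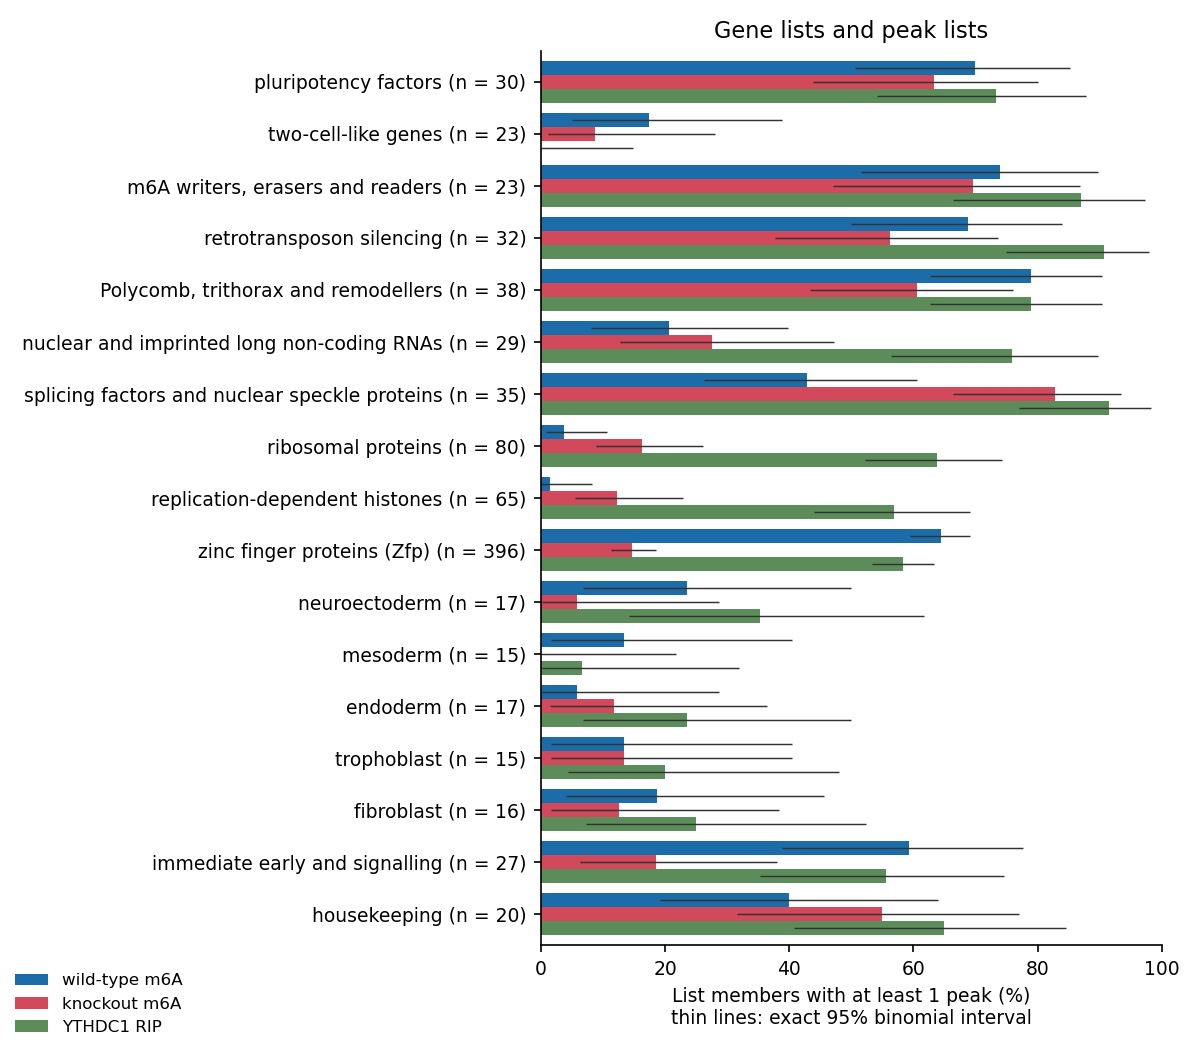
Share (%) of the members of 17 gene lists with at least 1 peak in the wild-type m6A, knockout m6A and YTHDC1 RIP lists, with n the matched members and thin lines the exact 95% binomial interval (counting error only). Zfp genes stand at 64.4% in the wild-type and 14.6% in the knockout list, splicing factors at 42.9% and 82.9%.

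YTHDC1 RIP peaks were found in the spans of nuclear RNA genes and of many coding genes. Malat1 and Neat1, the long non-coding RNAs of nuclear speckles and paraspeckles, held 5 RIP peaks each. The span of Xist held 2, and without strand these cannot be assigned to Xist rather than to an RNA from the opposite strand. All told 22 of 29 nuclear and imprinted long non-coding RNAs had a RIP peak (75.9%, 56.5 to 89.7%, Fisher's exact test, adjusted p = 5.9e-07). Among them were Lncenc1 with 8, Snhg14 with 7 and Rian with 6. A wild-type m6A peak was found in 6 of 29 and a knockout m6A peak in 8. The knockout count lay above that of other genes (odds ratio 2.96, exact test, adjusted p = 0.0245) but did not pass against span-matched random lists (adjusted permutation p = 0.0532) or with peaks above the median width (exact test, adjusted p = 0.271). RIP peaks lay in 32 of 35 splicing factor genes (exact test, adjusted p = 1.1e-13), with 13 in Luc7l2 and 11 in Rbm39, and in 29 of 32 genes of retrotransposon silencing (3.0e-12), with 14 in Rif1 and 9 in Tasor. They also lay in 51 of 80 ribosomal protein genes (exact test, 7.0e-10) and in 37 of 65 replication-dependent histone genes (7.0e-06). Both gene lists lay below other genes in the wild-type m6A list. Neither passed there against span-matched random lists (adjusted permutation p = 0.169 and 0.671). Another background was the genes with a peak in at least 1 list, which the RIP list helps select. Against it none of the gene lists named here passed in the RIP list (exact test, adjusted p = 0.0718 to 0.283). The labels give total RNA for the RIP samples and polyA RNA for the m6A samples. How far this accounts for gene list counts that differ between the RIP and m6A lists was not tested. Of the fixed genes Sox2 had 3 RIP peaks, Pou5f1 2, Nanog 1, Myc 1 and Klf4 0.

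Gene spans held 73.9% (73.4 to 74.4%) of the RIP peaks against 95.3% (94.9 to 95.7%) of the wild-type m6A peaks, an odds ratio of 0.139 (0.128 to 0.152). The RIP list held a group of very wide peaks. Its median width was 203 bp, yet 3829 peaks (12.4%) were 4 kb wide or more, with a median of 5851 bp, and they made up 74.7% of the bases covered. The widest in a named gene lay in Slc22a22, a member of the organic anion transporter family (10858 bp, chromosome 15, 57413510 to 57424367), followed by Kcnab1, a potassium channel subunit (8135 bp), Marchf1, a ubiquitin ligase (7897 bp), and Gpc6, a glypican (7829 bp). None of these had an m6A peak in either list. The placement of such wide peaks is in doubt (see the last paragraph). These genes are therefore named by position only, not as RNAs shown to be bound. Of the wide peaks 28.1% lay in gene spans against 82.4% of RIP peaks of 1 kb or less, and 9.98% lay on the X chromosome against 2.96% (odds ratio 3.63, 3.19 to 4.12, Fisher's exact test, adjusted p = 3.1e-74). The 1079 RIP peaks between these widths resembled the wide ones, with 31.0% in gene spans and 9.18% on the X chromosome. With peaks of 1 kb or less alone, a setting chosen after seeing the data, the odds ratio for gene spans was 0.231, and with peaks above the median width it was 0.0505.

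**Figure D3:**
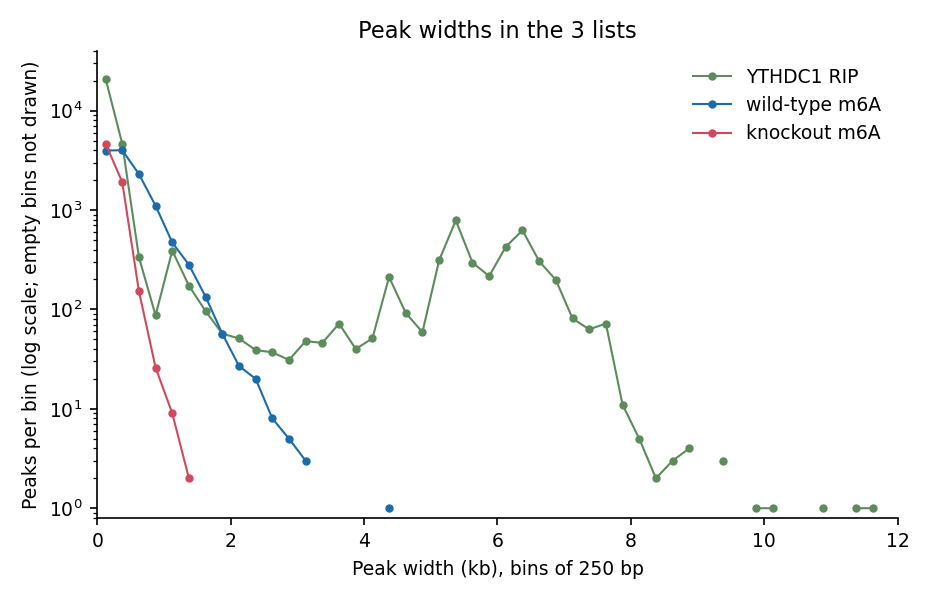
Number of peaks per 250 bp bin of peak width (log scale, empty bins not drawn) against width in kb, for the wild-type m6A, knockout m6A and YTHDC1 RIP lists. The RIP list has a separate group of wide peaks with a median of 5851 bp at 4 kb or more, while no m6A peak exceeds 4400 bp.

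YTHDC1 RIP peaks met m6A peaks of both genotypes more often than random positions in the same genes. In Sox2 a 220 bp RIP peak lay inside the 1300 bp wild-type m6A peak, and another overlapped the peak shared by both genotypes. In Neat1 both wild-type peaks overlapped a RIP peak, and in Malat1 the 350 bp wild-type peak did. No wild-type peak of Klf4, which had no RIP peak, or of Nanog overlapped one, and in Ythdc1 1 of 4 did. The Nanog RIP peak started at 122713626, within 100 bp of the end of the wild-type peak at 122713600. Of all RIP peaks 1748 (5.64%, 5.39 to 5.90%) overlapped a wild-type m6A peak and 1496 (4.83%, 4.59 to 5.07%) a knockout peak. Among those in gene spans 1649 overlapped the wild-type list against 741 ± 23.8 (SD over 1000 placements) at random, a ratio of 2.22, and 1417 overlapped the knockout list against 306 ± 16.6, a ratio of 4.63 (one-sided permutation p = 0.001 for each, the smallest that 1000 placements can give). Exon coordinates were not used, so how far shared exons account for these ratios was not tested. By the labels' protocol the RNA was not fragmented before the YTHDC1 pull-down. The place of a RIP peak within a gene therefore does not by itself locate YTHDC1 on the RNA.

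Among m6A peaks found in the wild-type list alone, 1373 of 10934 (12.6%, 11.9 to 13.2%) overlapped a RIP peak, against 300 of 1434 shared peaks (20.9%, 18.8 to 23.1%) and 1195 of 5319 knockout-only peaks (22.5%, 21.4 to 23.6%). Of the 10 widest wild-type-only peaks, those in Plec, Urgcp, Fem1a, Tnrc6c and Exoc8 overlapped one, and among the knockout-only ones those in Ptma and Gtf2f1, a subunit of TFIIF, did. The odds ratio of wild-type-only over knockout-only peaks was 0.496 (0.455 to 0.540, Fisher's exact test, two-sided, adjusted p = 1.1e-56), and that of wild-type-only over shared peaks 0.543 (0.472 to 0.624, adjusted p = 2.9e-16). Shared and knockout-only peaks gave 0.913 (0.792 to 1.05, exact test, adjusted p = 0.24). RIP peaks covered 5.57% of wild-type-only, 12.5% of shared and 18.9% of knockout-only midpoints. This was 4.61, 8.89 and 12.4 times the cover 2 to 5 kb away (1.21%, 1.40% and 1.52%). Those flanks ran along the chromosome, inside or outside the gene, and the classes differed in how often they lay near span ends. How far position in the gene sets these folds was not tested.

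**Figure D4:**
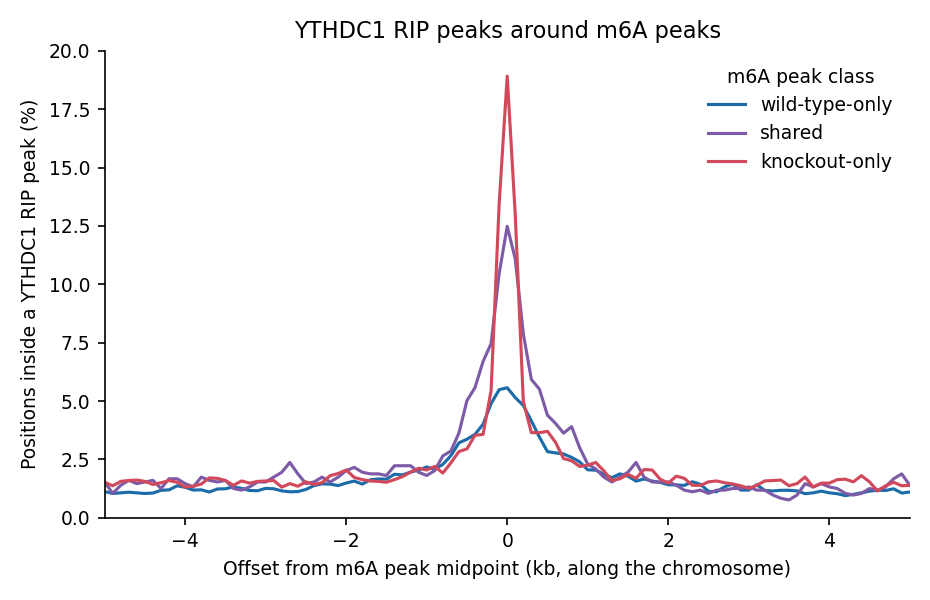
Share (%) of positions inside a YTHDC1 RIP peak against the offset in kb from the midpoint of wild-type-only, shared and knockout-only m6A peaks. All curves peak at the midpoint, at 5.57%, 12.5% and 18.9%.

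The 10 widest RIP peaks that met a wild-type-only m6A peak included those in Myo5b, an unconventional myosin (5326 bp, chromosome 18, 74750526 to 74755851), Cdh18, a cadherin (2755 bp), the cation channel gene Trpm3 (2255 bp), Zfp934 (2252 bp), the long non-coding RNA gene Platr10 (2166 bp) and Brd1, a subunit of a histone acetyltransferase complex (1811 bp). The exact width of the Myo5b peak recurs in 88 wide RIP peaks, whose placement is in doubt (see the last paragraph). Of the 3829 RIP peaks of 4 kb or more, 6 overlapped a wild-type m6A peak. At the level of genes, 4848 of 6570 genes with a wild-type m6A peak had a RIP peak (73.8%) against 18.2% of the other protein-coding and long non-coding RNA genes, an odds ratio of 12.7 (11.9 to 13.5). For genes with a knockout m6A peak it was 3040 of 3947 (77.0%) against 22.5%, an odds ratio of 11.5 (10.7 to 12.5). Expression was not used to choose the comparison genes. The wild-type odds ratio was 7.29 among protein-coding genes, 5.19 with peaks above the median width and 1.49 (1.29 to 1.74) among genes with a knockout m6A peak, the last a background chosen after seeing the data. Zfp genes, 231 of 396 with a RIP peak (58.3%), stood above other genes (odds ratio 3.53, Fisher's exact test, adjusted p = 1.8e-33). The odds ratio was 2.02 among protein-coding genes and 1.76 with peaks above the median width. Against genes with a peak in at least 1 list, which the RIP list helps select, it turned to 0.618 (exact test, adjusted p = 0.00226).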

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

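The settings on span-end distance, narrow RIP peaks, genes holding both classes, genes with a knockout peak and genes with a peak in at least 1 list were tests chosen only after the result was seen. Of 44 values under other settings, 39 kept their direction and side of the threshold, or stayed within their interval or within 1.5 times the main count. With peaks above the median width, the share of wild-type m6A peaks that overlap the knockout list was 5.48% in place of 11.6%, the rank correlation of widths in shared pairs was -0.115 in place of 0.0636, and the odds ratio of lying in gene spans, wild-type-only over knockout-only, turned from 0.901 to 1.56. With any overlap with a gene span that ratio was 0.769 and passed the threshold. With peaks above the median width fewer knockout peaks remain to be overlapped, which by itself lowers the first share. Beyond that, the cause was not tested for any of these. Against genes with a peak in at least 1 list 13 gene list tests passed in place of 28, with a background of fewer genes that the tested lists themselves select. The fold of RIP peaks over random placement ranged from 2.1 to 2.46 on the wild-type list and from 3.72 to 6.45 on the knockout list. Merging peaks that touch changed nothing, since none do. Placement within exons, exonic length and the motif settings were not run, because exons and sequence were not used here. No paired analysis was possible because the lists carry no values per replicate, and for the same reason no replicate could be left out. The unknown depth limits every comparison between the lists.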

Other observations

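The tests of shared signal near gene ends and the 3 tests on wide RIP peaks were chosen only after the result was seen, as were the genes named by number of peaks. By number of wild-type-only m6A peaks, the leading genes were Ahnak, which encodes a giant scaffold protein (23 wild-type-only and 2 knockout-only peaks), the atypical cadherin gene Fat1 (15 and 0), the cytolinker gene Dst (12 and 1), Mga, a partner of MAX (11 and 0) and the histone methyltransferase gene Kmt2d (10 and 0). By knockout-only peaks they were Mdn1, a ribosome assembly factor (12, against 3 wild-type-only), the translation factor gene Eif5b (10 against 1), Gigyf2 (10 against 1), the DNA methyltransferase gene Dnmt1 (9 against 0) and Fip1l1, a polyadenylation factor (9 against 0). By RIP peaks they were the cytolinker gene Macf1 (24), Rad51b, Ranbp17, Tex14 and Zfp993 (18 each) and Hells, a chromatin remodeller (17). Hells and Rad51b had no m6A peak in either list.

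On the X chromosome, the genes with most knockout m6A peaks were Huwe1, a ubiquitin ligase (6 knockout and 3 wild-type peaks), Upf3b, a factor of nonsense-mediated decay (6 and 0), Fam50a (5 and 1), and Gnl3l, Map7d2 and the paraspeckle protein gene Nono (5 and 0 each). The Y chromosome carried 94 of the 3829 RIP peaks of 4 kb or more against 17 of 26084 of 1 kb or less (odds ratio 38.6, 23.0 to 64.8), and 40 of the 1079 in between.

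Knockout-only m6A peaks lay near gene span ends more often than wild-type-only peaks. The tables argue against peak width as the whole cause, since among peaks 200 to 300 bp wide the odds ratio was 11.2 (9.19 to 13.6), and against different genes, since within the 1610 genes that hold both classes it was 17.0 (12.5 to 23.1). End signal that both lists call alike stays open: knockout peaks near an end overlapped a wild-type peak less often than other knockout peaks (18.2% against 22.7%, odds ratio 0.760, 0.664 to 0.870), but the comparison from the wild-type side goes the other way and only restates the share of shared peaks near ends. Also open are the peak threshold of each list and the genotype itself. A candidate explanation left untested, because strand was not used here, is cap-adjacent m6Am, which m6A antibodies also bind and METTL3 does not make.

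Wild-type-only m6A peaks overlapped a RIP peak less often than knockout-only peaks. Width did not account for it, since over bins of width the odds ratio was 0.347 (0.311 to 0.387). Nor did the choice of genes or peaks near span ends, with 0.461 (0.389 to 0.547) within genes that hold both classes and 0.505 (0.448 to 0.569) among peaks over 1 kb from both span ends. Signal that recurs in any pull-down of these RNAs may still contribute to both the knockout list and the RIP list, which was not tested because no Halo-GFP list was used here. No biological explanation was tested.

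The RIP peaks of 4 kb or more differed from those of 1 kb or less in place and chromosome, as did those in between. Long gene transcripts covered along their length are argued against, since 28.1% lay in gene spans against 82.4% of peaks of 1 kb or less. Merging of neighbouring signal stays open for the wide peaks in general. Of these, 1131 shared their exact width with 4 or more others, against 811 ± 39.6 (highest 973) in 1000 random shifts of each width by up to 25 bp. The count lay above every shift, which argues against merging as the only source of the repeated widths. The excess of 1.39 times fell short of the 2 times set as the bound after the result was seen. As a hypothesis, copies of retrotransposons could give repeated widths such as 5326 bp (88 peaks) and a surplus on the X chromosome, where the odds ratio over narrow peaks was 3.63 (3.19 to 4.12). This cannot be told apart from other sources here because no repeat annotation was used, and reads that fit several copies add to the doubt over where such peaks lie.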
